A study of Homo sapiens with 6 samples.

How the data were processed

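Poly(A) RNA was sequenced from HCE-2 human corneal epithelial cells in 6 libraries, 3 of untreated cells and 3 of cells kept with 90 mM NaCl for 24 h, here called control and hyperosmotic. Groups and replicate numbers were taken from the sample labels, and all 6 libraries were used. Total RNA was selected on oligo(dT) beads, per the labels' protocols, and the series' design text calls the 3 samples of a group biological replicates. The deposited file is a table of 34962 genes by Ensembl gene ID, with gene names, positions, GO and KEGG terms, and a count and an FPKM value for each library.

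The counts are whole numbers per gene that the authors deposited without normalization, per the file headers. The FPKM values (fragments scaled to gene length and library size) were computed by the authors and are given to 2 decimals, per the file headers. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR without a version and the genome build hg38, with no role or order. The counting tool, the annotation release, and whether strand was used are not given in the sources used here. Over 8956 genes with at least 200 counts and an FPKM of at least 1, the 2 kinds of value differed by 1 factor per gene and 1 per library, to within an SD of 0.0017 on the log2 scale. Low counts were piled up at multiples of 4: values of 4 were 2.03 times as frequent as the mean of values of 3 and 5, and values of 8 were 1.49 times as frequent as the mean of 7 and 9. A single fragment may therefore stand for several counts, so that counting error at low counts is larger than the counts imply. No row lacked a gene ID. Coordinates are printed as in the table, on hg38. Of its gene IDs, 94.8% were in GENCODE release 29, and 73.1% of those shared had the same start.

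Total counts were 82569994, 60180457 and 53409843 in control replicates 1 to 3 and 55861581, 57304529 and 61045473 in hyperosmotic replicates 1 to 3. Duplicated libraries were looked for and not found: the smallest chi-square per degree of freedom between libraries of the same group was 42.0. The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr (a minimum count of 10 and a minimum total of 15), a model with the group as the only term, and a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene is called, and said to rise or fall, at an adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 0.239. Levels are the authors' FPKM as mean ± SD over the 3 libraries of a group, and folds come from the edgeR fit. The limit that a count of 0 allows is 3 counts of the total, which covers counting error only and is too low where a fragment stands for several counts.

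Before the data were examined, 32 gene lists, the tests, the alternatives and a rule for naming genes were fixed. Lists with at least 5 tested members (28) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation. The directional test fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes, was run beside it. Members called were counted over all tested genes and with the p-values adjusted over the list alone. GO and KEGG terms with 10 to 300 tested genes were tested with a one-sided hypergeometric test against the tested genes that carry a term of that kind (13578 for GO and 5564 for KEGG), adjusted over all terms and both directions. The naming rule took the 10 largest rises and falls among called genes with a symbol, at least 5 FPKM in the higher group and no overlap between groups. It also took up to 3 called members of each list with the largest change plus the largest in each direction, the 5 smallest adjusted p, and 15 genes fixed in advance whether called or not (NFAT5, SLC5A3, SLC6A6, SLC6A12, AKR1B1, HSPA4L, IL1B, IL6, CXCL8, TNF, MMP9, NLRP3, KRT12, PAX6 and MKI67). Other genes named were chosen after their values were seen.

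The tests were tested on simulated data for this comparison of hyperosmotic with control libraries. Counts of 18263 genes were drawn from the real means, library sizes and dispersion, and 17775 genes passed the filter. The 200 genes changed were taken only from genes above a minimum abundance, so recovery of genes at a few counts was not measured. The edgeR test recovered 4.48% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 92.4% of those changed 4-fold, with 7 false calls (6.80% of its calls), and DESeq2 recovered 13.4%, 67.2% and 95.5% with 32 false calls (21.5%). In this simulation most genes changed 1.5-fold were therefore missed. It changed far fewer genes than the 2919 called in the real data. Recovery and the share of false calls depend on that number, so these rates do not carry over directly. Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter, a mean CPM of at least 5, a replicate block, an adjusted p under 0.01, each library left out in turn, and limma on log2(FPKM + 1) with a pseudocount of 0.1, TMM, quantile or same-sum scaling, array weights or robust variances. Added after seeing the data were counts divided by 4, total counts without scaling factors, limma on log2(FPKM + 1) as it is, a fit without mitochondrially encoded genes, and term enrichment with each library left out.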

Results

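Gene expression was measured by poly(A)-selected RNA sequencing in HCE-2 cells, a virus-immortalised human corneal epithelial line. The cells were left untreated or kept in hyperosmotic medium with 90 mM NaCl for 24 h, a culture model of the salty tear film of dry eye. Each of the 2 groups had 3 libraries, which the series describes as biological replicates. The control libraries held 82569994, 60180457 and 53409843 counts assigned to genes, and the hyperosmotic libraries held 55861581, 57304529 and 61045473. Of 34962 genes in the table, 30500 had a count above 0 in at least 1 library and 18263 were abundant enough to test. Over the tested genes, the Pearson correlation of log2 values was 0.970 to 0.977 between libraries of the same group and 0.942 to 0.956 between groups. The first principal component, which held 48.7% of the variance, separated the groups. Mitochondrially encoded genes took 9.54% to 10.8% of counts in controls and 8.36% to 10.03% in hyperosmotic libraries.

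The comparison asked how the transcriptome of HCE-2 cells differed after a day in hyperosmotic medium. Of the corneal identity genes, KRT12 had 0 counts in all 6 libraries and PAX6 was at 0.0467 FPKM in controls, while the keratin KRT5 was at 120 FPKM. Whether the changes of this line hold in corneal epithelium was not tested. Genes for the uptake or synthesis of organic osmolytes were among the largest rises. Of 20 endoplasmic reticulum chaperones 7 were higher and none lower, of 16 heat shock genes 5 and none, of 22 ribosome biogenesis genes 7 and none, and of 15 matrix protease genes 6 and 2. Camera called these 4 lists higher, but not with an estimated correlation (adjusted p of 0.178 to 0.222). Of 23 integrin subunits, 12 were higher and 3 lower. The cell cycle inhibitor CDKN1A, the immediate early gene EGR1 and 5 of 12 inflammasome-related genes fell. In all, 2919 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, of which 1580 were higher and 1339 lower in hyperosmotic medium. They made up 16.0% of the 18263 genes tested, a share to hold beside the counts of called list members. A change of at least 2-fold was seen in 829 of the higher and 451 of the lower genes. These numbers depended on the filter and the scale, with 440 and 185 at a mean CPM of at least 5 and 225 and 74 with limma on FPKM, where more genes were called lower (1204) than higher (1063). The median log2 fold change over all tested genes was 0.0054. The number of calls depended on single libraries. It was 1338 without hyperosmotic replicate 2, 1614 without hyperosmotic replicate 1, 1713 without control replicate 3 and 1843 without control replicate 1. Without hyperosmotic replicate 3 it was 2605, and without control replicate 2 it rose to 3508. Leaving out a library also lowers the number of samples.

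The osmoprotective list holds targets of the tonicity-responsive transcription factor NFAT5. Of its 10 members, 7 were higher and none was lower, and 8 were higher when adjusted over the list alone. SLC6A12, the betaine transporter (ENSG00000111181, chromosome 12, 190077 to 214570, hg38), rose from 0.0800 ± 0.0436 to 8.18 ± 0.551 FPKM (SD, n = 3 each). Its log2 fold change was 6.65 ± 0.37 (SE), with an edgeR adjusted p of 8.94e-07. AKR1B1, aldose reductase, which makes sorbitol (ENSG00000085662, chromosome 7, 134442356 to 134459284), rose 22.5-fold, from 119 ± 31.4 to 2637 ± 483 FPKM (SD, n = 3 each). It took 0.0340% to 0.0567% of all counts in the control libraries and 0.861% to 1.21% in the hyperosmotic ones. SLC5A3, the sodium-dependent inositol transporter (ENSG00000198743, chromosome 21, 34073578 to 34106260), rose from 0.587 ± 0.168 to 11.6 ± 2.83 FPKM. It lies within MRPS6 on the same strand, and MRPS6 rose from 20.7 ± 1.15 to 233 ± 18.7 FPKM, so the share of reads that belongs to each is uncertain. SGK1, a salt-responsive kinase, rose from 0.157 ± 0.0115 to 1.04 ± 0.0451 FPKM, and SLC38A2, a neutral amino acid transporter, from 9.19 ± 1.65 to 29.2 ± 7.43 FPKM. NFAT5 itself was at 1.14 ± 0.172 FPKM in controls and 1.63 ± 0.305 FPKM in hyperosmotic medium. Its log2 fold change of 0.56 ± 0.19 missed the threshold, with an edgeR adjusted p of 0.0640. With DESeq2 in place of edgeR, the adjusted p of NFAT5 was 0.0260. On simulated data 21.5% of the calls of DESeq2 were false, against 6.80% for edgeR. Far fewer genes were changed in that simulation than were called in the real data. Those shares therefore cannot tell whether the DESeq2 call of NFAT5 is false. Over all alternatives the adjusted p of NFAT5 ran from 0.00385 to 0.244. The taurine transporter SLC6A6 had a log2 fold change of 0.17 ± 0.15, and HSPA4L, a chaperone, one of 0.20 ± 0.29 (-0.16 without hyperosmotic replicate 1), and neither was called. In limma's camera test, which compares a list with all other genes at a preset inter-gene correlation of 0.01, this list was higher with an adjusted p of 1.35e-23. It was also the only one of the 28 lists tested to pass with an estimated correlation, at an adjusted p of 0.0245.

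**Figure D1:**
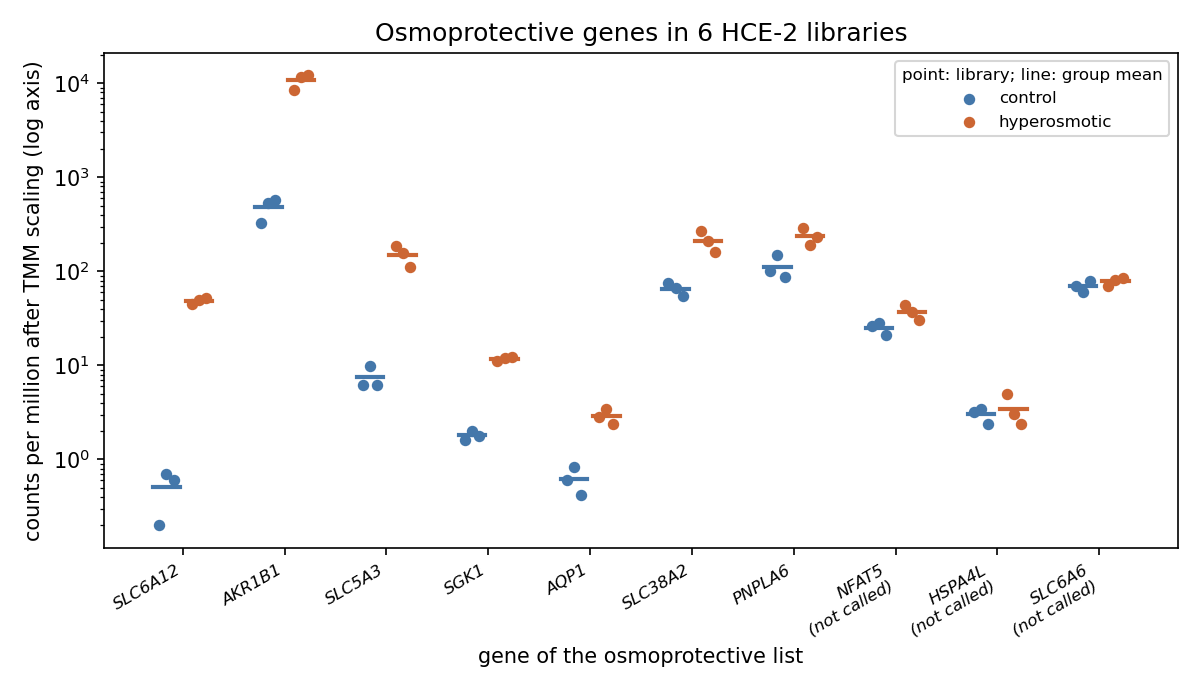
CPM (log axis) of the 10 osmoprotective genes in each library, with control libraries in blue, hyperosmotic libraries in orange and a line at each group mean of 3 libraries. The genes are ordered by log2 fold change, from SLC6A12 at 6.65 to SLC6A6 at 0.17, and the 3 genes at the right did not pass the test.

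Genes of ion transport and cell volume also differed, in both directions. Of 22 tested, 6 were higher and 3 lower (7 and 3 adjusted over the list alone). ATP1B1, a subunit of the sodium-potassium pump, rose from 2.75 ± 0.576 to 18.4 ± 0.857 FPKM (SD, n = 3 each), with a log2 fold change of 2.78 ± 0.17 (SE) and an edgeR adjusted p of 1.88e-06. The water channels AQP3 and AQP5 rose, AQP3 from 15.2 ± 2.51 to 33.8 ± 1.49 FPKM and AQP5 from 0.0433 ± 0.0153 to 0.917 ± 0.110 FPKM. AQP5 overlaps its antisense gene AQP5-AS1, which had a log2 fold change of 2.54, and the sources used here do not say whether strand was used in counting. The potassium-chloride cotransporter SLC12A4 fell from 18.5 ± 2.49 to 12.1 ± 0.467 FPKM, and SCNN1A, a subunit of the epithelial sodium channel, from 19.1 ± 1.19 to 12.8 ± 0.197 FPKM. Camera called the list higher with an adjusted p of 0.0174, and the adjusted p was 0.178 with an estimated correlation. On the authors' FPKM values, tested with limma, the adjusted p of this list was 0.234. Called members numbered 4 without hyperosmotic replicate 1 or 2 and 5 without control replicate 3, in place of 9. In the list of amino acid transport and serine synthesis, 3 of 15 genes were higher and 1 was lower (3 and 3 adjusted over the list alone), and the camera adjusted p was 0.454. The 3 were SLC38A2, SLC38A1 and the glycine transporter SLC6A9, which rose from 5.18 ± 0.477 to 12.1 ± 0.832 FPKM.

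Among all called genes with a gene symbol, at least 5 FPKM in the higher group and no overlap between the groups, the 10 largest rises included several genes outside the lists. CALB1, the calcium-binding protein calbindin (ENSG00000104327, chromosome 8, 90058608 to 90095475), rose from 0.0967 ± 0.0321 to 7.08 ± 0.879 FPKM (SD, n = 3 each), with a log2 fold change of 6.18 ± 0.27 (SE) and an edgeR adjusted p of 1.47e-07. COL5A3, a collagen chain, rose from 0.653 ± 0.280 to 22.8 ± 2.91 FPKM, and CCL26, an eosinophil chemokine, from 1.11 ± 0.591 to 39.1 ± 2.85 FPKM. The long noncoding RNAs LINC02582 and LINC02474 rose 24.3-fold and 17.0-fold, to 176 ± 3.20 and 145 ± 16.3 FPKM. ABHD12B rose 91.8-fold, to 28.4 ± 3.43 FPKM. It lies on the opposite strand within PYGL, which had a log2 fold change of -0.08 ± 0.16. An unnamed transcript, ENSG00000231412 (chromosome 19, 43328989 to 43331544), rose from 0.880 ± 0.185 to 50.5 ± 6.57 FPKM and was among the 5 genes with the smallest adjusted p.

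PIK3R2, a regulatory subunit of PI3-kinase, had a log2 fold change of 6.24 ± 0.32, and the overlapping gene ENSG00000268173 had one of -8.30 ± 0.28, with edgeR adjusted p of 4.54e-07 and 6.48e-08. The annotation in the table describes ENSG00000268173 as a readthrough between PIK3R2 and its neighbour IFI30, on the same strand. It held 23726, 21631 and 15318 counts in the control libraries and 42, 43 and 87 in the hyperosmotic ones. The counts summed over all 3 genes of the locus had a log2 fold change of -0.31 ± 0.14 and were not called, with an edgeR adjusted p of 0.150. The change in PIK3R2 is therefore uncertain as a change in its own expression.

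**Figure D2:**
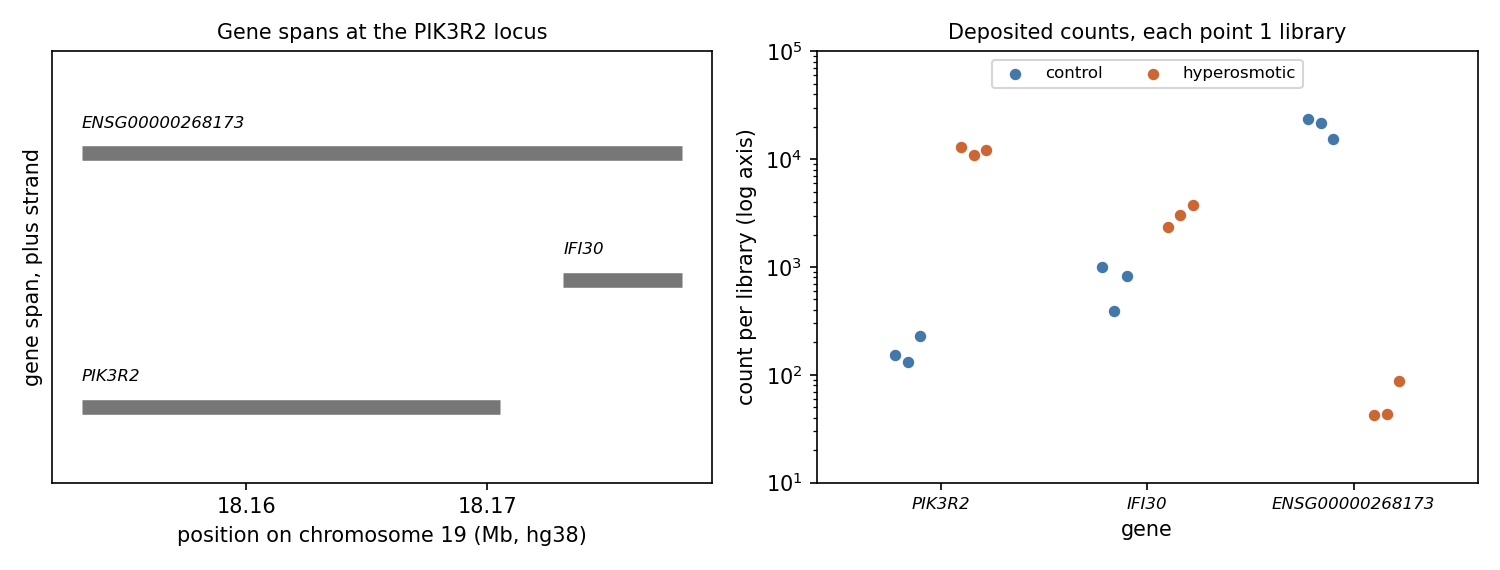
Left, spans of PIK3R2, IFI30 and the readthrough gene ENSG00000268173 on chromosome 19 (Mb, hg38). Right, deposited counts per library (log axis), with control libraries in blue and hyperosmotic libraries in orange, which show readthrough counts of 15318 or more in controls and 87 or fewer in hyperosmotic libraries, while PIK3R2 and IFI30 go the other way.

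Among genes with a gene symbol under the same limits, the 10 largest falls were led by EGR1, a growth-factor-induced transcription factor (ENSG00000120738, chromosome 5, 138465479 to 138469303), which went from 18.1 ± 0.894 to 2.24 ± 0.268 FPKM (SD, n = 3 each). Its log2 fold change was -2.98 ± 0.17 (SE), with an edgeR adjusted p of 9.12e-07. BMF, a pro-apoptotic BCL2-family gene, fell from 8.63 ± 0.818 to 1.69 ± 0.185 FPKM, and ACTA2, smooth muscle actin, from 12.6 ± 0.807 to 2.91 ± 0.128 FPKM. LBH, a transcription cofactor, fell from 18.4 ± 1.39 to 4.53 ± 0.304 FPKM. CDKN1A, which encodes the cell cycle inhibitor p21, fell from 80.2 ± 10.2 to 23.4 ± 0.486 FPKM. NEURL1B, LYPD1, CYP1A1, ZNF710-AS1 and SORCS2 fell 3.18-fold to 2.65-fold. Of these genes, ZNF710-AS1 overlaps ZNF710 on the other strand, which had a log2 fold change of -0.54.

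Protein folding was covered by 2 lists. Of 20 chaperones and folding factors of the endoplasmic reticulum, 7 were higher and none was lower (9 and 0 adjusted over the list alone). HSPA5, the luminal chaperone BiP, rose from 19.9 ± 4.15 to 61.6 ± 8.17 FPKM (SD, n = 3 each), with a log2 fold change of 1.66 ± 0.17 (SE) and an edgeR adjusted p of 9.76e-05. HSP90B1 rose from 12.8 ± 1.15 to 24.1 ± 6.90 FPKM. Camera called this list higher at an adjusted p of 0.00177, which was 0.222 with an estimated correlation. Of 16 heat shock genes, 5 were higher and none was lower (8 and 0 adjusted over the list alone). HSPH1 rose from 1.32 ± 0.0436 to 6.29 ± 1.91 FPKM, HSP90AA1 from 19.0 ± 1.32 to 46.9 ± 11.5 FPKM and HSPA4 from 12.6 ± 1.32 to 22.2 ± 1.11 FPKM. The camera adjusted p was 0.00214, and 0.178 with an estimated correlation. In the integrated stress response list 2 of 20 genes were higher and 2 lower (2 and 2 adjusted over the list alone), and the camera adjusted p was 0.712. Without control replicate 3, or without hyperosmotic replicate 1 or 2, 3 of the endoplasmic reticulum genes were called in place of 7, and without control replicate 1, 4 were. Called stress response genes numbered 0 without hyperosmotic replicate 1, 1 without hyperosmotic replicate 2 or 3 or control replicate 3, and 2 without control replicate 2.

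In the ribosome biogenesis list 7 of 22 genes were higher and none was lower, and 13 were higher when adjusted over the list alone. UTP20, a factor of small-subunit processing, rose from 0.357 ± 0.0252 to 1.27 ± 0.266 FPKM (SD, n = 3 each), with a log2 fold change of 1.85 ± 0.22 (SE) and an edgeR adjusted p of 0.000236. RRP9, which processes ribosomal RNA, rose from 11.9 ± 1.53 to 22.0 ± 2.41 FPKM, and the growth regulator MYC from 0.263 ± 0.0289 to 0.617 ± 0.0737 FPKM. The camera adjusted p was 0.00163, and 0.178 with an estimated correlation. The number of called members was 3 without hyperosmotic replicate 2, and 4 without hyperosmotic replicate 1 or control replicate 3.

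Matrix proteases and their inhibitors changed in both directions, with 6 of 15 higher and 2 lower (8 and 2 adjusted over the list alone). TIMP3, an inhibitor of metalloproteinases, rose from 4.41 ± 0.433 to 51.4 ± 1.38 FPKM (SD, n = 3 each), with a log2 fold change of 3.57 ± 0.15 (SE) and an edgeR adjusted p of 1.46e-07. It overlaps SYN3 on the other strand, which had a log2 fold change of 4.43. The interstitial collagenase MMP1 rose from 0.0533 ± 0.0252 to 4.46 ± 0.939 FPKM. The stromelysin MMP3 had 0 counts in all 3 controls and 14, 44 and 86 counts in the hyperosmotic libraries. The membrane-type protease MMP14 rose from 62.6 ± 7.35 to 123 ± 5.97 FPKM. The gelatinase MMP2 fell from 18.3 ± 2.48 to 7.82 ± 0.115 FPKM and urokinase, PLAU, from 26.7 ± 3.07 to 12.4 ± 0.681 FPKM. MMP9, the other gelatinase, was at 0.297 ± 0.170 and 0.240 ± 0.0557 FPKM, and its log2 fold change of -0.26 ± 0.47 (0.24 without control replicate 2) was not called. Camera called the list higher at an adjusted p of 3.07e-06, which was 0.178 with an estimated correlation.

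In the list of inflammatory cytokines and NF-kB targets, 3 of 17 genes were higher and 1 was lower (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.33. The list was not called by camera (adjusted p of 0.0787) or by limma's rotation test fry (adjusted p of 0.0515). The monocyte chemokine CCL2 rose from 0.490 ± 0.148 to 5.88 ± 0.369 FPKM (SD, n = 3 each), with an edgeR adjusted p of 5.11e-06. NFKBIA, an inhibitor of NF-kB, rose from 16.8 ± 1.46 to 40.1 ± 3.18 FPKM. IL1B was at 0.213 ± 0.0551 and 0.123 ± 0.118 FPKM, IL6 at 0.117 ± 0.0737 and 0.0633 ± 0.0153 FPKM, and CXCL8 at 0.0433 ± 0.0321 and 0.0633 ± 0.0115 FPKM, and none of these was called. TNF was too low to test and is not in these list tests, with 0 counts in the 3 controls and 20, 7 and 25 counts in the hyperosmotic libraries. Of 12 inflammasome and pyroptosis genes, 5 were lower and none higher (6 and 0 adjusted over the list alone). They were CASP1, GSDMB, NLRP1, TXNIP and IL18. GSDMB, a gasdermin, fell from 1.64 ± 0.361 to 0.673 ± 0.171 FPKM and NLRP1 from 0.377 ± 0.0153 to 0.187 ± 0.0404 FPKM. CASP1, the inflammatory caspase, fell from 0.390 ± 0.106 to 0.107 ± 0.0513 FPKM, but without control replicate 1 its edgeR adjusted p was 0.0732, and over all alternatives it ran from 0.00165 to 0.0732. NLRP3 was at 0.287 ± 0.0493 and 0.367 ± 0.0569 FPKM and was not called. Camera called the inflammasome list lower at an adjusted p of 0.0130, which was 0.463 with an estimated correlation. Without control replicate 1, 2 of its genes were called in place of 5, and 3 were without control replicate 3 or hyperosmotic replicate 1 or 2.

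Of 19 targets of p53, 7 were lower and 2 higher (10 and 2 adjusted over the list alone). Besides CDKN1A, these included DDB2, a DNA damage sensor, which fell from 39.6 ± 4.71 to 16.3 ± 2.26 FPKM (SD, n = 3 each), and BTG2, an antiproliferative gene, which fell from 23.7 ± 0.869 to 10.4 ± 0.980 FPKM. TP53INP1 fell from 0.220 to 0.0300 FPKM. TIGAR, a regulator of glycolysis, went the other way, from 0.797 ± 0.0306 to 1.5 ± 0.221 FPKM. Camera called the list lower at an adjusted p of 0.000856, which was 0.178 with an estimated correlation and 0.139 with limma on FPKM. In the DNA replication list, 5 of 25 genes were lower and 1 was higher (9 and 2 adjusted over the list alone). The licensing factor CDT1 fell from 48.4 ± 17.5 to 22.5 ± 5.47 FPKM. The camera adjusted p was 0.0149, and 0.463 with an estimated correlation. No member of this list was called without hyperosmotic replicate 2, where CDT1 had an edgeR adjusted p of 0.0674. CDT1 also lost its call without control replicate 1 (adjusted p of 0.0686) or hyperosmotic replicate 3 (adjusted p of 0.0515), and over all alternatives its adjusted p ran from 0.000186 to 0.0686. Called members numbered 2 without hyperosmotic replicate 1 or control replicate 3, 3 without control replicate 1 and 13 without control replicate 2. Of 25 mitosis genes, 5 were higher and none lower (5 and 0 adjusted over the list alone), with a camera adjusted p of 0.425. None of them was called without hyperosmotic replicate 1 or 2, and 1 was without control replicate 1 or 3. The proliferation marker MKI67 was at 6.30 ± 1.44 and 9.78 ± 3.12 FPKM and was not called, with an edgeR adjusted p of 0.0773, but it was called without hyperosmotic replicate 3 (adjusted p of 0.0160), and over all alternatives its adjusted p ran from 0.00181 to 0.245.

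**Figure D3:**
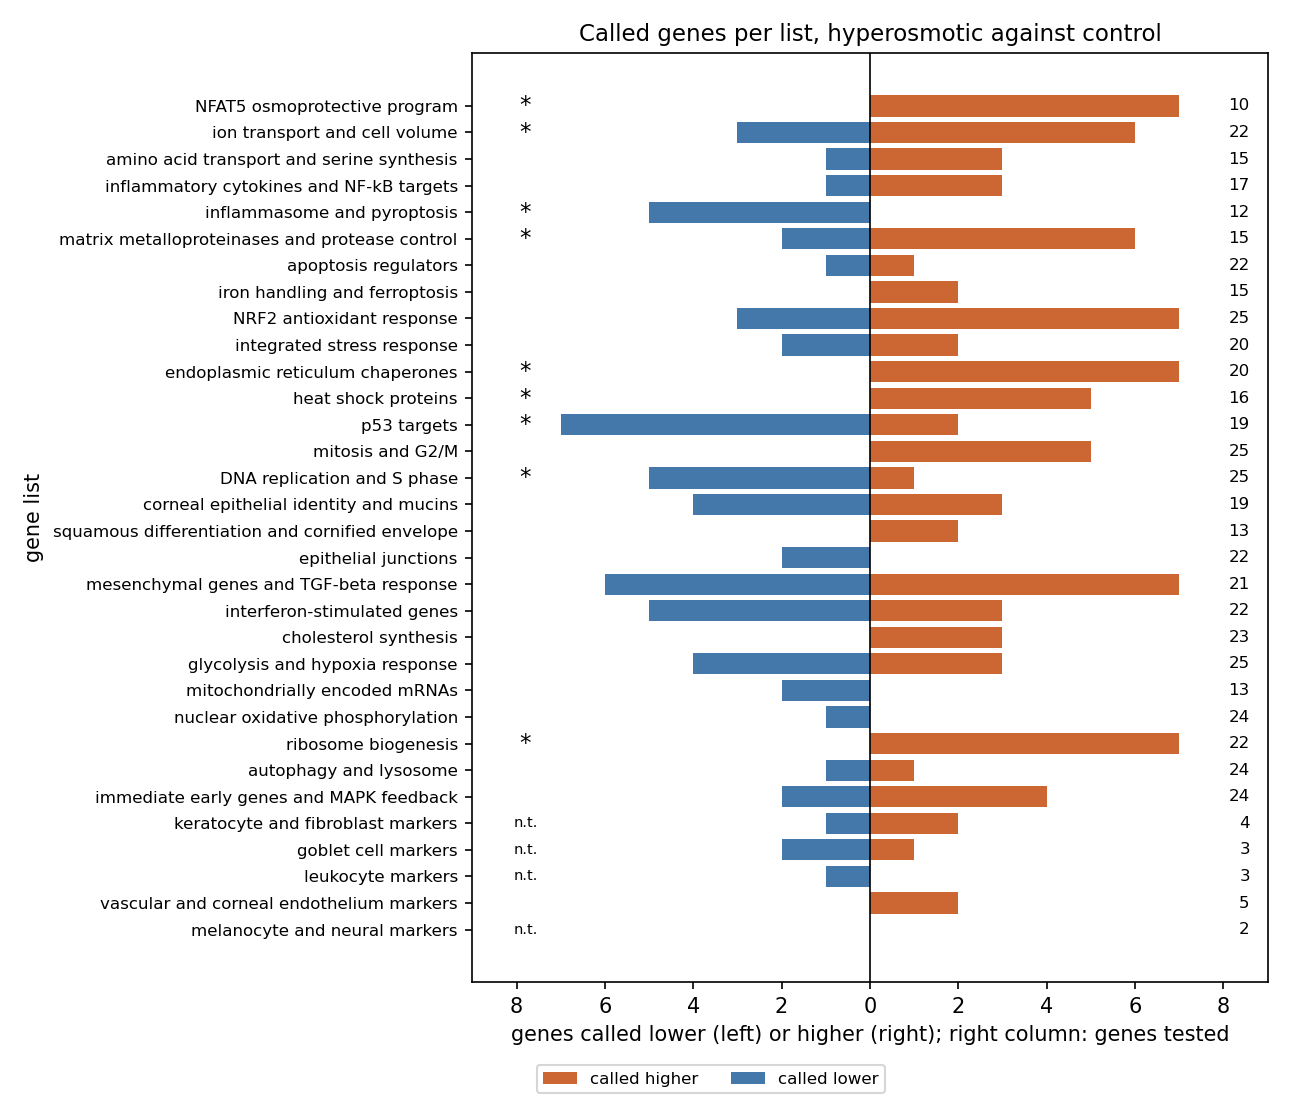
Number of genes called lower (left, blue) and higher (right, orange) by edgeR in each of the 32 gene lists, with the number tested in the right column. An asterisk marks the 9 lists called by camera with a preset correlation, of which the osmoprotective list alone was called with an estimated correlation, and n.t. marks the lists with fewer than 5 tested genes, which were not tested.

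In the list of corneal identity genes 3 of 19 tested genes were higher, 4 were lower and 12 were not called (3 and 5 adjusted over the list alone), and the camera adjusted p was 0.903. KRT12, the cornea-specific keratin, had 0 counts in all 6 libraries, which allows up to 0.0363 to 0.0562 CPM in a library if each count is 1 fragment, and more if a fragment stands for several counts. PAX6, the eye-field transcription factor, was at 0.0467 ± 0.0115 and 0.0267 ± 0.00577 FPKM (SD, n = 3 each) and was not called. KRT14, a basal keratin, rose from 0.0733 ± 0.0252 to 2.19 ± 0.315 FPKM, with an edgeR adjusted p of 2.15e-06, and KRT3, a keratin of differentiated corneal epithelium, had 9, 0 and 0 counts in controls and 41, 46 and 53 in hyperosmotic libraries, with an edgeR adjusted p of 0.00795. KLF4, an epithelial transcription factor, fell from 0.663 ± 0.124 to 0.253 ± 0.0252 FPKM. Many markers of other cell types were absent or too low to test, but some lay above KRT12, PAX6 and KRT3. The endothelial genes SLC4A11 and CDH5 went from 2.67 ± 0.277 to 6.74 ± 0.501 FPKM and from 1.92 ± 0.07 to 2.99 ± 0.275 FPKM. The leukocyte gene CSF1R fell from 2.56 ± 0.0802 to 0.98 ± 0.0436 FPKM, and the goblet cell gene AGR2 from 2.81 ± 0.333 to 0.757 ± 0.136 FPKM. In the fibroblast list COL3A1 had 0, 1 and 0 counts in controls and 54, 48 and 41 in hyperosmotic libraries, while COL1A1 fell from 3.12 ± 0.721 to 1.52 ± 0.438 FPKM. The fall of COL1A1 lost its call without control replicate 1 (adjusted p of 0.0661) or hyperosmotic replicate 2 (adjusted p of 0.0785), and over all alternatives its adjusted p ran from 0.000411 to 0.0785. Of 4 fibroblast genes tested, 2 were higher and 1 lower, of 3 goblet cell genes 1 and 2, of 3 leukocyte genes 0 and 1, and of 2 melanocyte and neural genes none. Adjusted over the list alone, the counts were the same except for 1 melanocyte and neural gene that was lower. Of 5 endothelial genes 2 were higher and none lower (also 2 and 0 adjusted over the list alone). The camera adjusted p was 0.225, while fry called this list higher with an adjusted p of 0.00448.

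The other lists were not called by camera. In the NRF2 antioxidant list 7 of 25 genes were higher and 3 lower (9 and 3 adjusted over the list alone), with an adjusted p of 0.137. AKR1C1 rose from 0.0200 ± 0.01 to 0.503 ± 0.159 FPKM and AKR1C3 from 0.0533 ± 0.0503 to 1.21 ± 0.246 FPKM (SD, n = 3 each). These are close paralogs, so counts for either are uncertain. Catalase, CAT, fell from 9.01 ± 2.77 to 4.23 ± 0.472 FPKM. In the mesenchymal and TGF-beta list 7 of 21 genes were higher and 6 lower (7 and 7 adjusted over the list alone), with an adjusted p of 0.712, and 8 were called without hyperosmotic replicate 1 or 2. TGFB2 rose from 0.333 ± 0.00577 to 1.04 ± 0.363 FPKM, and COL5A1, a fibrillar collagen chain, fell from 17.5 ± 3.10 to 7.09 ± 0.621 FPKM. Interferon-stimulated genes were 3 higher and 5 lower of 22 (3 and 5 adjusted over the list alone), with an adjusted p of 0.888. Leaving out single libraries gave as few as 2 called, without hyperosmotic replicate 2. IFIT2 rose from 0.703 ± 0.133 to 3.79 ± 0.941 FPKM but shares its strand with ENSG00000232110, which had a log2 fold change of 5.26. Glycolysis and hypoxia genes were 3 higher and 4 lower of 25 (3 and 5 adjusted over the list alone), with an adjusted p of 0.454. VEGFA rose from 1.45 ± 0.0173 to 3.56 ± 0.225 FPKM, and the hypoxia-induced carbonic anhydrase CA9 fell from 132 ± 23.0 to 68.7 ± 9.01 FPKM. Among immediate early genes 4 of 24 were higher and 2 lower (5 and 3 adjusted over the list alone), with an adjusted p of 0.967. The growth factor EREG rose from 0.390 ± 0.0755 to 3.22 ± 0.405 FPKM, against the fall of EGR1.

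In the remaining lists few genes passed. Cholesterol synthesis had 3 of 23 higher and 0 lower, and iron handling and ferroptosis 2 of 15 and 0, among them the transferrin receptor TFRC, which rose from 1.47 ± 0.245 to 4.01 ± 1.19 FPKM (SD, n = 3 each). Squamous differentiation had 2 of 13 higher and 0 lower, with PI3, the protease inhibitor elafin, rising from 0.597 ± 0.155 to 4.42 ± 0.159 FPKM. Apoptosis regulators had 1 of 22 higher and 1 lower, of which HRK fell from 0.643 ± 0.102 to 0.193 ± 0.0321 FPKM. Autophagy and lysosome genes had 1 of 24 higher and 1 lower, and in each of these 5 lists the counts adjusted over the list alone were equal. Epithelial junctions had 0 of 22 higher and 2 lower (1 lower adjusted over the list alone). Mitochondrially encoded mRNAs had 0 of 13 higher and 2 lower (also 2 adjusted over the list alone). Nuclear oxidative phosphorylation had 0 of 24 higher and 1 lower (0 adjusted over the list alone). Camera adjusted p in these 8 lists lay between 0.405 and 0.709. Without hyperosmotic replicate 2, 1 gene each of cholesterol synthesis, squamous differentiation and autophagy was called, and none of the junctions, the mitochondrially encoded mRNAs or oxidative phosphorylation.

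The annotation deposited with the table was also tested for enriched terms. Of 3530 GO and 314 KEGG terms, 40 were enriched among the higher genes and 13 among the lower ones, by a one-sided hypergeometric test with Benjamini-Hochberg adjustment. Without control replicate 1 these numbers were 79 and 25, and the number among the lower genes was 8 without control replicate 2 and 6 without hyperosmotic replicate 3. Integrin subunits stood first. Of 19 tested genes in the integrin complex term, 12 were higher (adjusted p of 0.000127). Examples, chosen after their values were seen, are ITGA6, a laminin receptor chain, which rose from 6.78 ± 1.06 to 21.1 ± 5.75 FPKM (SD, n = 3 each), and ITGA2, a collagen receptor chain, which rose from 0.570 ± 0.0200 to 2.29 ± 1.07 FPKM. Collagen-containing extracellular matrix had 45 of 215 genes higher (adjusted p of 0.000752), while collagen trimer had 14 of 49 lower (adjusted p of 0.0143). Ribosome biogenesis had 27 of 100 genes higher and structural constituent of chromatin, a term made up mostly of histones, 19 of 56, both at an adjusted p of 0.000752. The hypergeometric test takes genes as independent. Some histone genes had nearly the same counts, such as H4C14 (241, 167 and 139 in controls) and H4C15 (254, 169 and 145). The adjusted p of terms with genes that vary together may therefore be too small. Among the lower genes, the npBAF chromatin remodelling complex had 7 of 14 (adjusted p of 0.0189), and 0 of the 14 were called at a change of at least 2-fold. With only genes changed at least 2-fold, 17 terms were enriched among the higher and 2 among the lower genes. Of the terms named here, only collagen-containing extracellular matrix and structural constituent of chromatin passed there, and the chromatin term did not pass at a mean CPM of at least 5 (adjusted p of 0.0916). When single libraries were left out, integrin complex, collagen-containing extracellular matrix and structural constituent of chromatin passed each time. The ribosome biogenesis term did not pass without control replicate 1 or 3 or hyperosmotic replicate 2 (adjusted p of 0.0809, 0.162 and 0.796). Collagen trimer did not pass without hyperosmotic replicate 2 or 3 (0.104 and 0.254), and the npBAF term passed only without control replicate 1.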

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

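The alternatives with counts divided by 4, total counts only, plain limma on FPKM, no mitochondrially encoded genes, and terms with a library left out were chosen after the data were seen. Over the 21 alternatives, no gene called in the edgeR fit was called in the opposite direction, and 71 of 105 called genes that the naming rule took kept the call in every alternative that tested them, while 34 lost it in at least 1. For genes that were not called, leaving out single libraries gave a log2 fold change of -0.60 (without control replicate 3) to 0.24 (without control replicate 2) for MMP9 and of -0.16 (without hyperosmotic replicate 1) to 0.40 (without hyperosmotic replicate 3) for HSPA4L. The total of 2919 calls was 3835 with DESeq2 (2899 shared in direction), 2933 with upper-quartile factors, 2278 without the filter, 3265 with counts divided by 4 and 2830 with total counts only. At an adjusted p under 0.01 it was 1145, with 691 higher and 454 lower, and 270 lower at least 2-fold. Leaving out single libraries, which lowers the number of samples, gave 1338 to 3508 calls, 807 to 1790 higher and 531 to 1718 lower. The lowest came without hyperosmotic replicate 2 (1338) and the others under 1900 without hyperosmotic replicate 1 (1614), control replicate 3 (1713) and control replicate 1 (1843). The share of higher calls, 54.1%, was 46.9% with limma on FPKM, 47.6% with quantile scaling and 60.3% without hyperosmotic replicate 2. Genes changed at least 2-fold numbered 440 higher and 185 lower at a mean CPM of at least 5, which tests fewer genes. With limma on FPKM they numbered 225 and 74, with TMM scaling 238 and 62, with quantile scaling 216 and 75, with the same sum 236 and 71, with robust variances 222 and 67, with array weights 277 and 97, and with a pseudocount of 0.1 411 and 215, where 1045 genes in all were higher. Adding 1 to FPKM shrinks folds of low genes. Array weights gave 5859 calls, 2705 higher and 3154 lower, and the cause was not tested. Camera with an estimated correlation called 1 list in place of 9, and fry called 12 but not the inflammasome list (adjusted p of 0.0515). The estimated correlation was below the preset 0.01 in the heat shock list (-0.012) and the ion transport list (-0.019). The calls of these lists were therefore not lost through a higher correlation. It was above 0.01 in the other lists that lost the call. Fry alone called the endothelial, amino acid transport and iron handling lists higher (adjusted p of 0.00448, 0.00464 and 0.0357). It also called the apoptosis list lower (adjusted p of 0.0362). Fry run in either direction, which asks whether a list's genes change whatever their sign, called 26 of the 28 lists tested. With 16.0% of all tested genes called, that result sets few lists apart. The ion transport and p53 lists were not called with limma on FPKM (adjusted p of 0.234 and 0.139). Terms enriched among genes changed at least 2-fold numbered 19, of which 17 higher and 2 lower, from fewer called genes, and 11 of the 53 were among them. Leaving out single libraries gave 39 to 104 terms, 31 to 79 higher and 6 to 25 lower, with 23 to 41 of the 53 kept. Same-numbered libraries did not deviate together (correlations of -0.0012, -0.084 and 0.086), and a model with the replicate block called 2534 genes, 2410 of them shared. Depth limits genes at a few counts, such as TNF and MMP3.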

Other observations

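The tests of the histone, PIK3R2 and fibroblast patterns below were chosen after the result was seen, and the genes and families of the first 2 paragraphs after their values were seen. Clustered histone genes, most of which are expressed in step with DNA replication, were among the changed genes. Of 35 tested replication-dependent histone genes, 18 were higher and 1 lower, with a median log2 fold change of 1.78 and a range of -1.52 to 3.96. The number higher was 16 to 18 when single libraries were left out, and the lower one lost its call when any 1 of the 6 libraries was left out. The linker histone gene H1-2 rose from 34.4 ± 5.02 to 264 ± 19.6 FPKM (SD, n = 3 each), and H2BC12 rose from 19.5 ± 0.397 to 109 ± 9.92 FPKM. Of 8 histone genes that are expressed outside replication, 0 were higher and 1 was lower (0 or 1 higher and 0 to 2 lower when single libraries were left out), with a median log2 fold change of -0.02, which was 0.04 without control replicate 2. The pregnancy-specific glycoprotein genes also rose, 8 of 9 tested, and the counts summed over this family of near-identical genes had a log2 fold change of 1.53 ± 0.16 (SE). Of 23 integrin subunit genes tested, 12 were higher and 3 lower, and without control replicate 3 the number higher was 8.

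Single genes outside the lists rose as well. CDH16, a cadherin, rose from 0.167 ± 0.0764 to 2.19 ± 0.104 FPKM (SD, n = 3 each), and the water channel gene AQP2 from 0.0800 ± 0.0265 to 0.440 ± 0.0436 FPKM, although AQP2 overlaps AQP5-AS1. S100A4, a calcium-binding protein, rose from 15.5 ± 2.11 to 80.6 ± 10.03 FPKM. Among abundant transcripts, the simple-epithelial keratin KRT18 rose from 373 ± 30.4 to 683 ± 22.3 FPKM. KRT7 was lower, at 712 ± 140.1 and 472 ± 29.1 FPKM, but lost its call when any library except control replicate 1 was left out (adjusted p of 0.0598 to 0.0996). The noncoding RNA UCA1 rose from 340.03 ± 39.1 to 885 ± 78.1 FPKM, and ALPP, placental alkaline phosphatase, from 733 ± 145 to 1215 ± 81.9 FPKM.

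The histone rise was set against 3 explanations. Reads moving between near-identical copies would leave the family's sum about level, but the counts summed over the 35 genes had a log2 fold change of 2.60148 ± 0.14 (SE). Carry-over of RNA without a poly(A) tail would raise other such RNAs, but the summed counts of RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1 had a log2 fold change of 0.061163 ± 0.26. More cells in S phase would raise genes that are expressed throughout that phase. The upper quartile of the DNA replication list was -0.021987 and its median -0.31, so this list did not rise as a whole. Whether its genes stay high through all of S phase was not tested. These values therefore cannot tell whether more cells were in a later part of S phase, and that explanation stays open. The summed counts argue against reads moving between copies and against carry-over as the whole cause. No explanation beyond these 3 was tested.

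The 75.7-fold rise of PIK3R2 was weighed against a shift of counts between overlapping genes. The counts summed over PIK3R2, IFI30 and the readthrough gene had a log2 fold change of -0.311902 ± 0.14 (SE), which is what a shift of counts within the locus needs and argues against a rise of transcription over the locus. Whether the cells switched from the readthrough to separate transcripts, or the reads of similar transcripts were assigned differently, stays open, since read-level data were not analysed here. There were 7 pairs of called genes that overlap on the same strand and changed at least 2-fold in opposite directions. They held 13 genes, since the readthrough gene is paired with both PIK3R2 and IFI30. In 6 of the 7 pairs the summed counts changed by less than 1 in log2. The pairs were chosen for opposite changes, so each sum lies between the 2 changes and is drawn toward 0. This count therefore cannot tell whether counts shifted within the pairs. The exception was IFI30 with the readthrough gene, at -2.59.

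The collagen and metalloproteinase genes called higher from fewer than 100 counts on average in controls were MMP1, COL3A1, COL1A2 and MMP3, of which COL1A2 (log2 fold change of 4.59, and 8.18 without control replicate 3) lost its call without control replicate 1 or hyperosmotic replicate 1 (adjusted p of 0.0629 and 0.0513). RNA from fibroblasts would bring abundant fibroblast transcripts with it, and of 7 listed, VIM, DCN and THY1 were low enough in controls to show a small share, while COL1A1 and SPARC were not and LUM and POSTN were not in the table. In hyperosmotic libraries VIM had 0, 0 and 28 counts (13, 15 and 14 in controls), DCN 0, 0 and 0 and THY1 4, 2 and 0, against 599, 802 and 991 for MMP1 and 54, 48 and 41 for COL3A1. The summed CPM of these 3 transcripts was 0.245 in controls and 0.188 in hyperosmotic medium, and the upper 95% limit of its rise was 0.0342081 of the rise of MMP1, which argues against RNA from fibroblasts as the source of MMP1. For COL3A1, COL1A2 and MMP3 that limit was 0.212289 of their rise, so RNA from fibroblasts stays open for them, because at these counts the spread of VIM between libraries is too wide.

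With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. In each count below, 1 of the 10 splits, the real one, reached the real value. It called 2919 genes, and the highest of the other splits called 1. It called 1280 genes changed at least 2-fold, against 1 in the highest other split, and 53 terms, against 0. For the gene lists, camera with a preset correlation called 9 in the real split and 7 in each of 2 others, which set control replicate 1 with control replicate 2 or 3 and hyperosmotic replicate 1. Those splits called at most 1 gene. Every split other than the real one has control and hyperosmotic libraries on both sides. Part of the difference between control and hyperosmotic stays in such a split, and the rest widens the spread within its groups. Few gene calls are therefore due in the other splits whatever the cause. Whether their list calls come from the part that stays cannot be told from these splits.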
